A study of Mus musculus with 12 samples.

How the data were processed

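RNA sequencing of mouse ES cells was deposited as 12 tables, 1 per library, in 6 groups of 2: unmodified cells in serum/LIF or 2iL and GSK3 knockout cells in serum/LIF, each with DMSO or with 100 nM JQ1 for 60 h. Per the file headers and the authors' notes the values are expected counts per gene, which the authors estimated with RSEM from reads aligned by STAR and did not scale to depth. The columns scaled to depth and length were not used. The authors' notes name bcl2fastq, STAR 2.5.2, RSEM, DESeq2 1.18.1 and the mm10 genome, and do not state the annotation release, strand setting or filters. Each table lists 52550 gene identifiers, and between 6.11% and 8.71% of values per library were not whole, as fits counts shared between genes. Of the identifiers 49035 matched GENCODE mouse release M 21 (GRCm 38) with their version and 52403 (99.72%) without it, and symbols and coordinates were taken from that release.

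Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16987. Libraries were scaled by TMM, and 1 quasi-likelihood fit of the 6 groups had 6 residual degrees of freedom, a common biological coefficient of variation of 0.129 and a median prior of 6.8 degrees of freedom. This fit gives each gene 1 spread for all 6 groups. The spread between libraries over counting error (chi-square per gene) was not equal. It was 32.2 with DMSO and 41.3 with JQ1 in unmodified serum/LIF, 25.9 and 8.78 in 2iL, and 10.4 and 9.96 in the knockout. The measure also grows with depth. Counts of genes that passed are therefore not strictly comparable between settings. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F. That of a list's median is the SD of medians over random draws of its genes with replacement (bootstrap). It treats genes as independent and leaves out the spread between libraries. The 7 comparisons were JQ1 against DMSO in each of 3 settings, 2iL against serum/LIF, knockout against unmodified cells, and the differences of the JQ1 response in 2iL or in the knockout from that in unmodified serum/LIF cells.

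The 19 gene lists, with 236 genes, were naive pluripotency, general pluripotency, formative and primed, Wnt target, MEK-ERK target, mesendoderm, primitive endoderm, neuroectoderm, trophoblast, two-cell-like, fibroblast feeder, germline, DNA methylation machinery, G2/M cell cycle, p53 target, ribosome biogenesis, cholesterol synthesis, glycolysis, and BET, elongation and Mediator. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 133 tests, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance and compares them with no other genes. Camera called 55 lists, 25 higher and 30 lower, and 0 with an estimated correlation. In 18 of 133 tests the median, mean and test differed in sign, and 0 of these passed. The text names the 5 highest and 5 lowest log2 fold changes of each comparison among genes that passed with at least 5 CPM in a group, members of the lists, and a fixed set including Gsk3a, Gsk3b, Ctnnb1, Axin2, Myc, Brd2 and Brd3.

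Library totals ran from 17869865 to 48723436 expected counts. A gene with no counts in a group was set at a floor of 3 counts per library for folds, and floors cover counting error only. The test was tried on simulated counts with 200 changed genes in each of 3 runs. In the design of JQ1 in serum/LIF it recovered 61% of genes changed by log2 1 and 80.7% of those changed by log2 2, and 7.41% of calls were unchanged genes. For the difference in 2iL these were 36%, 65.7% and 3.79%, and for that in the knockout 34.7%, 66% and 7.65%. Each of the list tests called the simulated changed list in 3 of 3 runs and 0 of 54 unchanged lists. The simulated genes varied independently, whereas the naive list, for example, had an estimated correlation of 0.367. The simulation therefore does not show how often the list tests err when genes of a list vary together.

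Alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, a stricter filter of 1 CPM in 4 libraries, a log2 fold change of at least 1, only the libraries compared, the replicate number as a block, Spearman rho, and each library left out in turn. A fit without mitochondrially encoded genes, and one of only genes at 5 CPM or more in unmodified 2iL cells with DMSO, were chosen after seeing the data. With a library left out its group holds 1 library, which is assumed to vary like the other groups. No library was excluded.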

Results

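Messenger RNA was measured by sequencing in mouse embryonic stem (ES) cells, and the values deposited are expected counts per gene. The 12 libraries fall into 6 groups of 2. Cells with no knockout in their label, called unmodified here, were grown in serum/LIF or in 2iL, and GSK3 knockout cells were grown in serum/LIF. LIF is the cytokine that sustains ES cell self-renewal, and 2iL adds inhibitors of the kinases MEK and GSK3 to a serum-free medium. GSK3 marks beta-catenin, the effector of Wnt signalling, for destruction. Each of the 3 settings was treated for 60 h with 100 nM JQ1, which displaces bromodomain proteins of the BET family, among them Brd2 and Brd3, from acetylated histones, or with the solvent DMSO. Serum/LIF cells had been kept on mouse fibroblasts and were moved to gelatin before the experiment, whereas 2iL cells grew on gelatin, so medium and feeder history differ together.

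Library totals ran from 17869865 to 48723436 expected counts. The deepest library was the first unmodified serum/LIF DMSO replicate, and the next deepest held 29882439. Mitochondrially encoded genes took 10.64% ± 1.7 (SD, n = 2) of counts in unmodified serum/LIF with DMSO and 6.98% ± 0.75 with JQ1. The share was 6.58% ± 0.24 and 4.74% ± 0.11 in 2iL, and 10.91% ± 0.35 and 7.82% ± 0.87 in the knockout. Levels below are CPM, counts scaled to library size, as mean ± SD with n = 2 libraries, and changes are log2 fold changes ± standard error. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Where 1 count is given for a list, that adjusted over the list alone was the same. The groups, the 7 comparisons and their tests, the 19 gene lists and the rule for naming genes were set before the data were examined.

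The targeted genes were examined first in the libraries labelled GSK3 knockout. Gsk3a (ENSMUSG00000057177.12, chromosome 7, 25228258 to 25237851, GRCm38) stood at 71.0 ± 8.23 CPM in unmodified serum/LIF cells and at 24.1 ± 0.973 CPM in the knockout with DMSO. Gsk3b (ENSMUSG00000022812.13, chromosome 16, 38089001 to 38246084) stood at 73.5 ± 1.8 and 46.9 ± 6.13 CPM. Gsk3a fell by 1.56 ± 0.13 on the log2 scale (adjusted p = 2.08e-06) and Gsk3b by 0.65 ± 0.13 (adjusted p = 0.00165). Over single libraries Gsk3a ran from 23.4 to 32.9 CPM in the 4 knockout libraries and from 65.1 to 130 CPM in the 8 unmodified ones, and Gsk3b from 42.5 to 61.1 and from 72.2 to 158 CPM. The transcripts were lower but still present, and counts over a whole gene do not show which part was deleted.

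**Figure D1:**
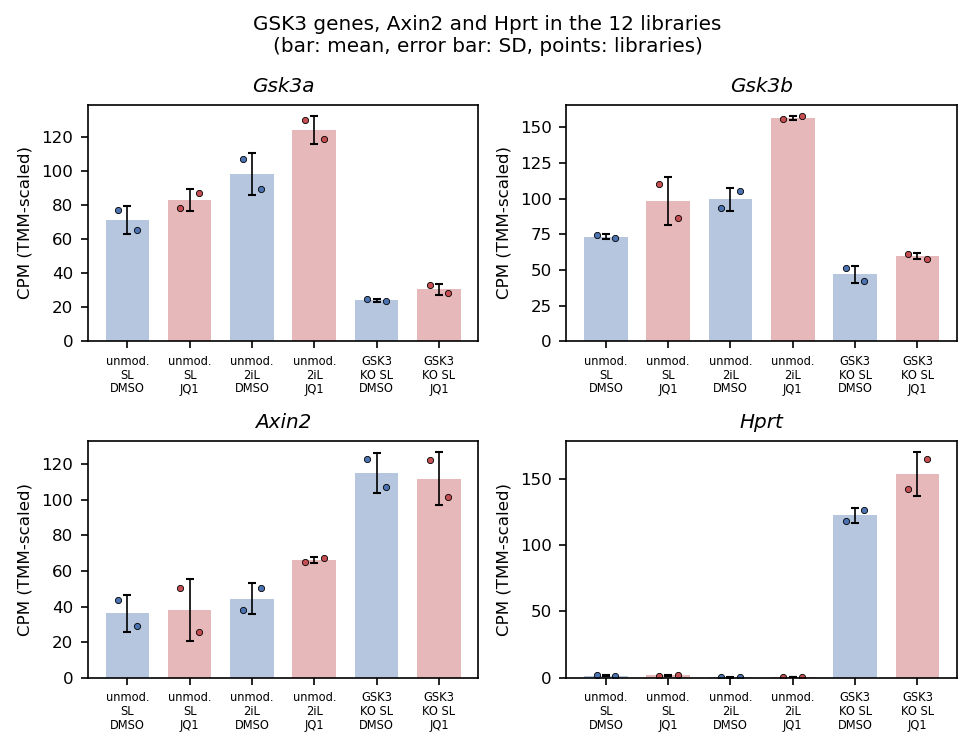
Levels of Gsk3a, Gsk3b, Axin2 and Hprt in CPM on the vertical axis for the 6 groups on the horizontal axis, where bars are means, error bars are SD and points are the 2 libraries of each group. Gsk3a fell from 71.0 to 24.1 CPM and Hprt rose from 1.69 to 122 CPM between unmodified and knockout cells in serum/LIF with DMSO.

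The comparison of JQ1 with DMSO in unmodified serum/LIF cells asks what BET inhibition does outside the ground-state medium. Naive pluripotency genes fell as a group. Nanog (ENSMUSG00000012396.12, chromosome 6, 122707489 to 122714633), a core factor of the naive state, went from 157 ± 24.1 to 51.9 ± 10.8 CPM, a log2 change of -1.60 ± 0.15. Nr5a2, a nuclear receptor that sustains pluripotency, fell by 2.92 ± 0.19, and Prdm14, a repressor of differentiation genes, fell by 4.09 ± 0.56. Prdm14 was low, at 2.2 and 4.71 CPM in the DMSO libraries and 0.130 and 0.242 CPM in the JQ1 libraries. The JQ1 values lie near the floor of 3 counts (0.13 and 0.145 CPM), so the size of its fall is uncertain. Tcl1, a cofactor of the kinase Akt, fell by 3.06 ± 0.35 and the transcription factor Klf4 by 0.96 ± 0.14. Of the 16 naive genes tested 13 fell and 1 rose, over all genes and adjusted over the list alone, with a median of -1.003 (adjusted p = 8.1e-06, and adjusted p = 0.415 with an estimated correlation). Dppa3 (0.16 ± 0.36) and Klf5 (-0.06 ± 0.12) did not pass. Esrrb fell by 0.74 ± 0.21, but lost its call in the fit of these 4 libraries alone (adjusted p = 0.0898) and without DMSO replicate 2 (-0.32, adjusted p = 0.3) or JQ1 replicate 1 (-0.46, adjusted p = 0.173). Among 9 general pluripotency genes only Tdgf1, a Nodal coreceptor, passed (-1.11 ± 0.21), and the list's median was 0.03 (adjusted p = 0.742). Pou5f1 (-0.07 ± 0.17) and Sox2 (0.17 ± 0.23) did not pass.

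Mesendoderm genes fell in the same comparison, 10 of 11 tested, with a median of -2.27 (adjusted p = 1.13e-06, and adjusted p = 0.415 with an estimated correlation). Lefty2, a secreted inhibitor of Nodal signalling, dropped from 259 ± 65.6 to 9.67 ± 1.52 CPM, and Gsc, a homeobox gene of the organizer, fell by 3.27 ± 0.64. All 4 tested genes of the two-cell-like state fell (adjusted p = 0.000513, and adjusted p = 0.415 with an estimated correlation). Zscan4f stood at 8.43 ± 4.47 CPM with DMSO and at 0.114 ± 0.0237 CPM with JQ1, and Zscan4c was at least 43.5-fold lower against a floor of 3 counts per library. The Zscan4 genes are near-identical copies, so the split of reads between them is uncertain. Notum, a secreted Wnt antagonist, fell by 3.63 ± 0.25, whereas Axin2, a feedback target of beta-catenin, did not pass (0.07 ± 0.26). Krt42, a keratin gene, fell (-5.62 ± 0.55) to 0.186 ± 0.079 CPM, near the floor of 3 counts. It was among the 5 genes that fell furthest of those with at least 5 CPM in a group that the naming rule allowed.

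Cholesterol synthesis genes rose in serum/LIF, 8 of 15 over all genes and 9 adjusted over the list alone, with a median of 0.40 (adjusted p = 7.27e-05, and adjusted p = 0.415 with an estimated correlation). Examples were Sqle (0.68 ± 0.10) and Hmgcs1 (0.63 ± 0.13), both enzymes of the pathway, and Insig1 (0.59 ± 0.10), its feedback sensor. Brd2 rose from 274 ± 21.8 to 521 ± 46.1 CPM, a change of 0.92 ± 0.10, while Brd3 (0.11 ± 0.12) did not pass. In the list of BET, elongation and Mediator genes 3 of 17 rose, 4 adjusted over the list alone, and none fell (adjusted p = 0.0116, and adjusted p = 0.423 with an estimated correlation). That list call was lost without JQ1 replicate 1 (adjusted p = 0.0872). The linker histone genes H1f0 (1.76 ± 0.17) and H1fx (1.69 ± 0.18), the early growth response gene Egr1 (1.80 ± 0.27) and the kinase gene Wnk2 (1.88 ± 0.21) were among the genes that rose most. Ctnnb1 (chromosome 9, 120929216 to 120960507), which encodes beta-catenin, rose by 0.52 ± 0.09, with adjusted p = 0.057 in the fit of these 4 libraries alone. Myc (0.33 ± 0.14) and Gsk3a (0.22 ± 0.13) did not pass.

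Fibroblast genes, chosen as markers of feeder cells, fell alongside these groups, 9 of 12 over all genes, with 9 lower and 1 higher adjusted over the list alone (adjusted p = 0.000576, and adjusted p = 0.415 with an estimated correlation). The collagen gene Col3a1 went from 42.6 ± 1.86 to 8.21 ± 3.87 CPM and Postn fell by 2.59 ± 0.36, whereas Tagln (461 ± 142 and 719 ± 233 CPM) and Acta2 (338 ± 81 and 312 ± 108 CPM), genes of contractile cells, did not pass. Of the p53 targets 4 of 12 fell, 9 adjusted over the list alone, among them Cdkn1a, a cell cycle inhibitor gene (-1.05 ± 0.21, list adjusted p = 0.0133, and adjusted p = 0.598 with an estimated correlation). Of the germline genes 5 of 12 fell, among them the meiotic gene Hormad1 (-2.15 ± 0.36, list adjusted p = 0.034, and adjusted p = 0.507 with an estimated correlation). In primitive endoderm 4 of 14 fell (adjusted p = 0.0381, and adjusted p = 0.598 with an estimated correlation). Of the glycolysis genes 3 of 14 rose (adjusted p = 0.0246, and adjusted p = 0.598 with an estimated correlation). The calls of these last 4 lists were lost without 1 library: p53 without DMSO replicate 1 (adjusted p = 0.153) or JQ1 replicate 2 (0.0685), germline without DMSO replicate 2 (0.0547) or JQ1 replicate 1 (0.154), primitive endoderm without DMSO replicate 1 (0.102) or JQ1 replicate 2 (0.416), and glycolysis without JQ1 replicate 2 (0.0894). Fry also lost those of p53 targets (adjusted p = 0.0509) and primitive endoderm (0.0726).

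The remaining lists did not pass in serum/LIF. In the formative and primed list 4 of 13 rose and 4 fell (adjusted p = 0.987): Dnmt3b, a de novo DNA methyltransferase, rose by 0.77 ± 0.13 and the growth factor gene Fgf5 fell by 2.08 ± 0.31. Of 8 DNA methylation genes 2 rose and 1 fell (adjusted p = 0.514), the latter being Tet1, a 5-methylcytosine oxidase (-1.32 ± 0.22). Wnt targets (2 of 14 rose and 4 fell, 5 adjusted over the list alone, adjusted p = 0.299) and MEK-ERK targets (4 of 14 rose and 1 fell, adjusted p = 0.264) went both ways. Trophoblast (2 of 8 fell, adjusted p = 0.35), neuroectoderm (1 of 8 fell, adjusted p = 0.68), G2/M cell cycle (1 of 12 rose, 0 adjusted over the list alone, adjusted p = 0.424) and ribosome biogenesis genes (2 of 15 rose and 1 fell, adjusted p = 0.196) mostly did not pass. In all, 3623 of 16987 genes passed in this comparison, 1450 higher and 2173 lower, and at a log2 fold change of at least 1 these were 163 and 1521. The count was 2245 in the fit of these 4 libraries alone (588 higher and 1657 lower), 2305 and 1927 without DMSO replicate 1 or 2, and 2393 without JQ1 replicate 1.

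The same treatment in 2iL asks whether the ground-state medium alters the response. Nanog stood at 801 ± 63.4 CPM with DMSO and at 938 ± 42.7 CPM with JQ1 and did not pass (0.23 ± 0.14), nor did Klf4 (0.30 ± 0.14), Esrrb (0.53 ± 0.21), Pou5f1 (-0.06 ± 0.17) or Sox2 (0.43 ± 0.23). In the naive list 4 of 16 rose, among them Tbx3, a transcription factor of the naive state (0.66 ± 0.11), and Dppa3, a maternal-effect gene (2.03 ± 0.39), and Tcl1 fell by 1.35 ± 0.25. Adjusted over the list alone 8 rose and 1 fell, with a median of 0.39 (adjusted p = 0.00836, and adjusted p = 0.577 with an estimated correlation), a call lost with fry (adjusted p = 0.145). Glycolysis genes rose together, 12 of 14 over all genes and 13 higher with 1 lower adjusted over the list alone. Their median was 0.73 (adjusted p = 1.44e-08, and adjusted p = 0.415 with an estimated correlation). Pfkl, a phosphofructokinase, went from 67.1 ± 1.06 to 235 ± 17.2 CPM, and Ldha (1.44 ± 0.12), Pgk1 (1.15 ± 0.10) and the glucose transporter gene Slc2a1 (1.10 ± 0.18) rose too.

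Lefty1 (-6.85 ± 0.60) and Lefty2 (-6.99 ± 0.62) fell in 2iL. With JQ1, Lefty1 stood at 0.301 ± 0.184 and Lefty2 at 0.517 ± 0.489 CPM, so the size of these falls is uncertain. Germline genes fell, 10 of 12 over all genes and 11 adjusted over the list alone, with 1 higher by either and a median of -1.75 (adjusted p = 0.000261, and adjusted p = 0.415 with an estimated correlation). The meiotic gene Sycp3 fell by 3.70 ± 0.40 as did Sohlh2, a germ cell transcription factor gene (-2.57 ± 0.21). All 4 two-cell-like genes fell (adjusted p = 0.00148, and adjusted p = 0.415 with an estimated correlation), with Zscan4c at 11.7 ± 9.62 and 0.108 ± 0.152 CPM. Brd2 rose by 1.00 ± 0.10 and Aff4, a scaffold of the elongation machinery, by 1.05 ± 0.15. In their list 10 of 17 rose, 13 adjusted over the list alone (adjusted p = 7.27e-05, and adjusted p = 0.415 with an estimated correlation). Brd3 (-0.20 ± 0.12), Myc (-0.47 ± 0.18), Axin2 (0.57 ± 0.26) and Gsk3a (0.34 ± 0.13) did not pass, while Ctnnb1 rose by 0.48 ± 0.09 and Gsk3b by 0.66 ± 0.13.

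Among the genes that rose most in 2iL were Dnmt3l, a cofactor of DNA methyltransferases (3.83 ± 0.40), the linker histone gene Hist1h1c (2.55 ± 0.22), the imprinted gene Peg10 (2.46 ± 0.34) and the growth factor gene Kitl (2.20 ± 0.31). Of the DNA methylation list 4 of 8 rose, 5 adjusted over the list alone, and 1 fell, with Dnmt3b at 1.08 ± 0.13 (list adjusted p = 0.0281, and adjusted p = 0.415 with an estimated correlation). The list call was lost without DMSO replicate 1 (adjusted p = 0.0979). Of the MEK-ERK targets 5 of 14 rose and 0 fell, with 1 lower adjusted over the list alone, and Spry2, a feedback inhibitor of the pathway, rose by 1.04 ± 0.14 (list adjusted p = 0.0147, and adjusted p = 0.423 with an estimated correlation). Of these 14 targets 6 were under 1 CPM in 2iL with DMSO and had little room to fall. Of 12 fibroblast genes 11 were under 1 CPM in 2iL with DMSO, so that list has little signal there. In all, 4834 genes passed, 1896 higher and 2938 lower, and 243 and 2146 at a log2 fold change of at least 1. The count was 2926 without DMSO replicate 1, 2688 without JQ1 replicate 1 and 2530 without JQ1 replicate 2.

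**Figure D2:**
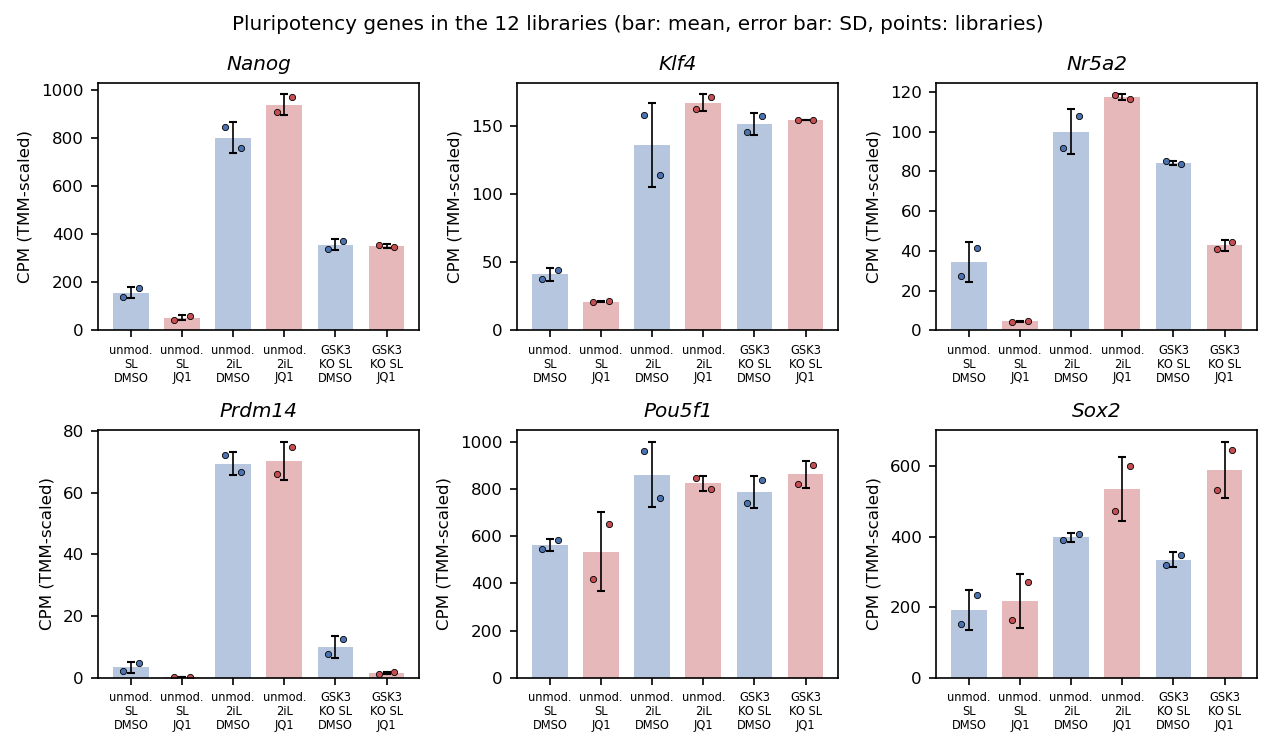
Levels of 6 pluripotency genes in CPM on the vertical axis for the 6 groups on the horizontal axis, where bars are means, error bars are SD and points are the 2 libraries of each group. Nanog fell from 157 to 51.9 CPM with JQ1 in unmodified serum/LIF cells and stood at 801 and 938 CPM in 2iL.

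Whether loss of GSK3 without the 2iL medium alters the response was addressed with JQ1 in knockout cells in serum/LIF. Nanog stood at 356 ± 22.8 and 351 ± 8.52 CPM and did not pass (-0.02 ± 0.14), nor did Klf4 (0.03 ± 0.14), Esrrb (0.33 ± 0.21) or Pou5f1 (0.13 ± 0.17). Of the 16 naive genes 6 fell and 2 rose, over all genes and adjusted over the list alone, and the list did not pass (median -0.28, adjusted p = 0.273). Those that fell included Prdm14 (-2.70 ± 0.34), the growth factor gene Fgf4 (-1.90 ± 0.19), Tcl1 (-1.65 ± 0.27) and the nuclear receptor gene Nr0b1 (-1.20 ± 0.24). Tdgf1 fell by 1.71 ± 0.22. Sox2 rose by 0.82 ± 0.23 but lost its call without DMSO replicate 1 (adjusted p = 0.0919) or JQ1 replicate 2 (adjusted p = 0.102). Lefty2 (-7.51 ± 0.61), Lefty1 (-6.22 ± 0.68) and Nphs1, the nephrin gene (-7.95 ± 0.63), fell. With JQ1, Nphs1 stood at 0.09 ± 0.0302 and Lefty1 at 0.197 ± 0.0361 CPM. These levels lie near the floor of 3 counts (0.103 and 0.167 CPM), so the size of both falls is uncertain. Of 11 mesendoderm genes 4 fell, 5 adjusted over the list alone, including Nodal (-1.55 ± 0.18) and Eomes (-1.59 ± 0.19), with list adjusted p = 0.0252 and adjusted p = 0.415 with an estimated correlation. Sox21, a neural transcription factor gene, went from 1.60 ± 0.183 to 28.9 ± 2.24 CPM. It was among the 5 genes allowed by the naming rule that rose most. Slc25a4, the mitochondrial ADP/ATP carrier, rose by 2.30 ± 0.16 and Hist1h1c by 2.25 ± 0.23.

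Glycolysis genes rose in the knockout, 10 of 14 with either adjustment, including adjusted over the list alone (median 0.46, adjusted p = 0.000149, and adjusted p = 0.415 with an estimated correlation). Gapdh went from 3895 ± 211 to 6594 ± 125 CPM, Pgk1 rose by 0.71 ± 0.10 and Pfkl by 0.62 ± 0.10. Cholesterol synthesis genes went both ways, 5 of 15 lower, 6 adjusted over the list alone, and 2 higher (adjusted p = 0.273), with the reductase gene Dhcr7 at -0.77 ± 0.12. Foxd3, a forkhead transcription factor gene, fell by 4.30 ± 0.40, and the 5-methylcytosine oxidase genes Tet1 and Tet2 fell by 1.90 ± 0.23 and 2.37 ± 0.24. Of the germline genes 8 of 12 fell and 1 rose, with Sycp3 at -2.54 ± 0.40 (list adjusted p = 0.00526, and adjusted p = 0.423 with an estimated correlation). Of the primitive endoderm genes 8 of 14 fell, 10 adjusted over the list alone (adjusted p = 0.00832, and adjusted p = 0.505 with an estimated correlation). Fibroblast genes fell here too, 8 of 12 (adjusted p = 0.00145, and adjusted p = 0.415 with an estimated correlation), with Col3a1 at 12.8 ± 5.53 and 0.613 ± 0.395 CPM, Thy1 at -1.56 ± 0.28 and Tagln, which did not pass, at -0.46 ± 0.27.

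Of the BET, elongation and Mediator genes 5 of 17 rose and 2 fell in the knockout (adjusted p = 0.444). Hexim1, an inhibitor of the elongation factor P-TEFb, rose by 0.58 ± 0.10, its partner Larp7 by 0.81 ± 0.15 and Ctnnb1 by 0.56 ± 0.09. Brd2 rose by 0.38 ± 0.10 but lost its call without any 1 of the 4 libraries (adjusted p from 0.059 to 0.0656). Myc fell by 0.41 ± 0.14 and lost its call without DMSO replicate 1 (adjusted p = 0.0783), DMSO replicate 2 (0.2) or JQ1 replicate 1 (0.33). Brd3 (0.27 ± 0.12), Axin2 (-0.04 ± 0.25), Gsk3a (0.35 ± 0.14) and Gsk3b (0.34 ± 0.13) did not pass. In all, 5799 genes passed, 2485 higher and 3314 lower, and 297 and 2178 at a log2 fold change of at least 1. More passed in the fit of the 4 knockout libraries alone, 7329 genes, 3596 higher and 3733 lower. The count was 3186 without DMSO replicate 1, 3420 without JQ1 replicate 1 and 3270 without JQ1 replicate 2.

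**Figure D3:**
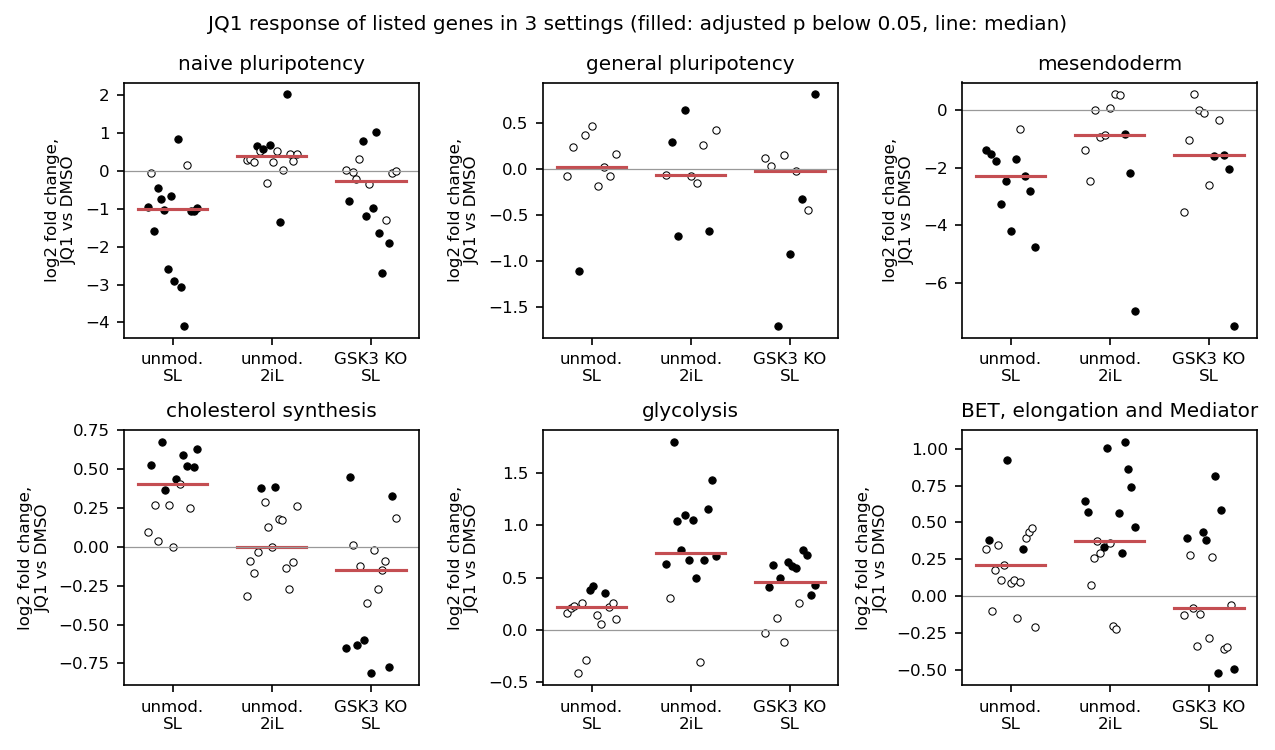
Log2 fold change of JQ1 against DMSO on the vertical axis for each gene of 6 lists in the 3 settings on the horizontal axis, where filled points passed the test and red lines are medians. The naive list had a median of -1.003 in unmodified serum/LIF cells, 0.39 in 2iL and -0.28 in the knockout, and glycolysis 0.21, 0.73 and 0.46.

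The difference between the response in 2iL and that in serum/LIF was tested as an interaction. Naive genes stood higher in the response of 2iL cells, 13 of 16 over all genes and 15 adjusted over the list alone, with a median difference of 1.47 (adjusted p = 2.87e-12, and adjusted p = 0.415 with an estimated correlation). The difference was 4.11 ± 0.64 for Prdm14, 3.15 ± 0.25 for Nr5a2, 2.27 ± 0.38 for Nr0b1, 1.82 ± 0.20 for Nanog and 1.26 ± 0.20 for Klf4. For Prdm14 its size is uncertain, since that gene was near the floor with JQ1 in serum/LIF. That of Esrrb (1.27 ± 0.30) passed, but not in the fit of these 8 libraries alone (adjusted p = 0.09). Esrrb also lost its call without serum/LIF DMSO replicate 2 (adjusted p = 0.0876), serum/LIF JQ1 replicate 1 (0.0597), 2iL DMSO replicate 1 (0.0779), 2iL JQ1 replicate 1 (0.0801) or 2iL JQ1 replicate 2 (0.102). Pou5f1 (0.01 ± 0.24), Sox2 (0.26 ± 0.32) and Klf5 (0.38 ± 0.17) did not pass. Glycolysis genes also differed, 7 of 14 and 10 adjusted over the list alone, all higher in 2iL (adjusted p = 1.21e-07, and adjusted p = 0.415 with an estimated correlation), with Pfkl at 1.58 ± 0.14 and Ldha at 1.184 ± 0.17. The mesendoderm genes Eomes (2.27 ± 0.28) and Nodal (1.46 ± 0.23) differed the same way, 2 of 11 in their list, with 4 higher and 1 lower adjusted over the list alone (list adjusted p = 0.000122, and adjusted p = 0.415 with an estimated correlation). Of that list 6 of 11 genes were under 1 CPM in 2iL with DMSO and had little room to fall there.

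Ceacam1, an adhesion receptor gene, differed by 4.76 ± 0.63 and Dnmt3l by 3.54 ± 0.48. Mmp14, a membrane-bound matrix protease, stood at 119 ± 10.1 and 88.5 ± 16.5 CPM in serum/LIF and at 13.0 ± 0.49 and 0.407 ± 0.149 CPM in 2iL, a difference of -4.60 ± 0.33. The difference of Plekha6, a gene of a pleckstrin homology domain protein, was -5.62 ± 0.47. Myc (-0.80 ± 0.23), Brd2 (0.08 ± 0.14), Brd3 (-0.31 ± 0.17), Axin2 (0.51 ± 0.37) and Ctnnb1 (-0.04 ± 0.13) did not pass. In all, 706 genes differed, 230 higher and 476 lower. DESeq2 called 1014, 418 higher and 596 lower, and with no low-count filter 1478 differed, 522 higher and 956 lower. The count was 431 in the fit of these 8 libraries alone, 468 without serum/LIF DMSO replicate 2, 383 without 2iL JQ1 replicate 1 and 330 without 2iL JQ1 replicate 2. The log2 fold changes with JQ1 in the 2 media correlated across genes, which are not independent replicates, with Pearson r = 0.566 and Spearman rho = 0.554, but r was 0.272 over the 30185 genes kept with no low-count filter. Both comparisons called 1163 genes lower (376 for independent lists) and 710 higher (162), and 73 went opposite ways (493).

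The interaction of JQ1 with the knockout is taken from the same 4 unmodified serum/LIF libraries as that with 2iL, so chance in them moves both alike. Across genes the 2 interactions correlated with Pearson r = 0.33 and Spearman rho = 0.233, where simulated unchanged groups gave r = 0.47 ± 0.016 (SD of 20 simulations). The covariance was 0.403 against 0.163 simulated, a difference of 0.24, part of which may come from the shared libraries. All simulated libraries were drawn from the mean levels of unmodified serum/LIF cells with DMSO. They lack the levels of the other groups, so the simulated values are a rough guide only. Of the naive genes 5 of 16 stood higher in the response of knockout cells and 1 lower, 9 and 2 adjusted over the list alone (median 1.00, adjusted p = 0.000576, and adjusted p = 0.457 with an estimated correlation). Nr5a2 differed by 1.94 ± 0.25, the threonine dehydrogenase gene Tdh by 1.81 ± 0.26 and Nanog by 1.58 ± 0.20. Klf4 differed by 0.99 ± 0.20 and lost its call without unmodified DMSO replicate 2 (adjusted p = 0.0532), knockout DMSO replicate 1 (0.082), knockout JQ1 replicate 1 (0.0693) or knockout JQ1 replicate 2 (0.0658). Esrrb (1.07 ± 0.30), Pou5f1 (0.20 ± 0.24) and Sox2 (0.65 ± 0.32) did not pass. Cholesterol synthesis genes stood lower, 7 of 15 and 12 adjusted over the list alone, with a median of -0.67 (adjusted p = 1.13e-06, and adjusted p = 0.415 with an estimated correlation). Dhcr7 differed by -1.02 ± 0.17 and Srebf2, the regulator of the pathway, by -0.96 ± 0.16. Sox21 differed by 3.85 ± 0.37, Fgf8 by 3.60 ± 0.49 and Notum by 2.82 ± 0.33, and Kbtbd11 by -4.32 ± 0.34, the calcium pump gene Atp2a3 by -4.14 ± 0.34 and Foxd3 by -3.12 ± 0.51.

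Hprt, the purine salvage gene, set the knockout libraries apart from the unmodified ones in every treatment, with 1.69 ± 0.434 CPM in unmodified and 122 ± 5.67 CPM in knockout cells with DMSO. In this interaction 742 genes differed, 212 higher and 530 lower, and DESeq2 called 1350, 540 higher and 810 lower. The share of higher calls was thus 28.6% by edgeR and 40% by DESeq2. With no low-count filter 2011 differed, 732 higher and 1279 lower. Each left-out library moved the count: 340 and 489 without unmodified DMSO replicate 1 or 2, 403 and 1779 without unmodified JQ1 replicate 1 or 2, 226 and 397 without knockout DMSO replicate 1 or 2, and 212 and 232 without knockout JQ1 replicate 1 or 2. Brd2 (-0.54 ± 0.14) passed with adjusted p = 0.0489 and not with RLE scaling (adjusted p = 0.064), in the fit of these 8 libraries alone (0.0684), or without any library but unmodified JQ1 replicate 2 (adjusted p from 0.064 to 0.173). Myc (-0.74 ± 0.20), Axin2 (-0.11 ± 0.36) and Ctnnb1 (0.04 ± 0.13) did not pass. The JQ1 responses of unmodified and knockout cells in serum/LIF correlated across genes with Pearson r = 0.532 and Spearman rho = 0.507, but r was 0.218 with no low-count filter and 0.625 with the stricter one. Both called 1281 genes lower (424 for independent lists) and 715 higher (212), and 63 went opposite ways (601).

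Between 2iL and serum/LIF without JQ1, naive genes were higher in 2iL, 14 of 16 over all genes and 15 adjusted over the list alone, with 1 lower by either (median 1.83, adjusted p = 7.38e-06, and adjusted p = 0.415 with an estimated correlation). Prdm14 rose by 4.43 ± 0.30, Tbx3 by 3.38 ± 0.12, Tfcp2l1, a transcription factor of the ground state, by 3.31 ± 0.17, Nanog by 2.35 ± 0.15, Esrrb by 2.61 ± 0.22 and Klf4 by 1.73 ± 0.14. MEK-ERK targets were lower, 11 of 14 with 3 higher (median -3.44, adjusted p = 0.000301, and adjusted p = 0.415 with an estimated correlation). The phosphatase gene Dusp4 (-6.85 ± 0.37), the feedback inhibitor gene Spry4 (-6.28 ± 0.26), Egr1 (-5.35 ± 0.41) and Myc (-3.53 ± 0.16) fell. In the formative and primed list 9 of 13 were lower and 1 higher (adjusted p = 0.00245, and adjusted p = 0.423 with an estimated correlation), with Pou3f1 at 105 ± 15.2 and 1.06 ± 0.322 CPM, Fgf5 at -5.92 ± 0.43 and Dnmt3b at -3.39 ± 0.14. Dnmt3l fell by 7.84 ± 0.37, while Uhrf1, which recruits the maintenance methyltransferase, rose by 1.33 ± 0.10. The general pluripotency genes Lin28a (-3.75 ± 0.22) and Utf1 (-2.89 ± 0.19) fell, and Sox2 rose by 1.04 ± 0.23.

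Marker lists of several other cell types were lower in 2iL. All 12 fibroblast genes fell, with a fitted median of -10.67, or -6.55 with 6 genes at their bound (adjusted p = 4.85e-09, and adjusted p = 0.415 with an estimated correlation). Tagln stood at 461 ± 142 CPM in serum/LIF and 0.0919 ± 0.0648 CPM in 2iL, and Col3a1 was at least 309-fold lower against a floor of 3 counts per library. Of the trophoblast genes 7 of 8 fell and 1 rose (adjusted p = 0.00258, and adjusted p = 0.415 with an estimated correlation), with the keratin genes Krt8 and Krt18 at -7.83 ± 0.45 and -8.47 ± 0.44. Of the primitive endoderm genes 10 of 14 fell and 2 rose, with 11 lower adjusted over the list alone (adjusted p = 0.00779, and adjusted p = 0.505 with an estimated correlation), including the collagen gene Col4a1 (-5.37 ± 0.33). Of the mesendoderm genes 9 of 11 fell and 1 rose, with 10 lower adjusted over the list alone (adjusted p = 0.00101, and adjusted p = 0.415 with an estimated correlation), with Wnt3 at -7.79 ± 0.51. The neuroectoderm list did not pass (4 of 8 lower and 1 higher, adjusted p = 0.188, and adjusted p = 0.000138 with fry), nor did the two-cell-like list (adjusted p = 0.685), in which 0 of 4 genes passed by edgeR, with or without adjustment, or by DESeq2. Germline genes were higher, 7 of 12 (adjusted p = 0.00324, and adjusted p = 0.415 with an estimated correlation), with the tubulin gene Tuba3a at 6.45 ± 0.19 and the RNA-binding protein gene Dazl at 5.06 ± 0.21.

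Of the cholesterol synthesis genes 10 of 15 were higher in 2iL and 1 lower (adjusted p = 0.00836, and adjusted p = 0.539 with an estimated correlation), with Insig1 at 1.99 ± 0.11. Of the G2/M genes 9 of 12 were higher (adjusted p = 0.0292, and adjusted p = 0.423 with an estimated correlation), a call lost without serum/LIF DMSO replicate 2 (adjusted p = 0.0561) or 2iL DMSO replicate 1 (0.051). Glycolysis genes went both ways, 8 of 14 lower and 4 higher (adjusted p = 0.273), with Slc2a1 at -2.96 ± 0.19 and the hexokinase gene Hk1 at 2.505 ± 0.12. Wnt targets did too, 6 of 14 lower and 4 higher (adjusted p = 0.445), with the transcription factor gene Lef1 at -4.26 ± 0.36 and Axin2 not passing (0.28 ± 0.26). The methyltransferase gene Bhmt (9.52 ± 0.58) and the meiosis gene Stra8 (8.19 ± 0.54) were among the genes that rose most. Brd2 (-0.03 ± 0.10), Brd3 (0.27 ± 0.12) and Klf5 (0.29 ± 0.12) did not pass. In all, 9311 genes passed, 4802 higher and 4509 lower, but which direction held more genes depended on the processing. More were lower with RLE scaling (4262 higher and 4874 lower), with DESeq2 (4068 and 4555), with no low-count filter (4835 and 4844), in the fit of these 4 libraries alone (3662 and 4191) and at a log2 fold change of at least 1 (2141 and 3233). More were lower also without mitochondrially encoded genes (4410 and 4756), a fit chosen after seeing the data, and without serum/LIF replicate 1 (3838 and 3856) or 2 (4041 and 4132) or 2iL replicate 1 (3809 and 4360) or 2 (4057 and 4338). Among the settings in which more were higher was the stricter filter (4152 and 3867). Pou5f1 (0.61 ± 0.17), Ctnnb1 (0.27 ± 0.09), Gsk3a (0.46 ± 0.13) and Gsk3b (0.44 ± 0.13) passed, but each lost its call when 1 library was left out: Pou5f1 without serum/LIF replicate 1 (adjusted p = 0.0577) or 2iL replicate 1 (0.112), Ctnnb1 without serum/LIF replicate 2 (0.139) or 2iL replicate 1 (0.158) or 2 (0.0666), Gsk3a without serum/LIF replicate 2 (0.0803) or 2iL replicate 1 (0.125), and Gsk3b without serum/LIF replicate 2 (0.0593) or 2iL replicate 2 (0.132).

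The knockout was compared with unmodified cells in serum/LIF without JQ1. Of the 16 naive genes 15 were higher and 1 lower in the knockout with either adjustment, including adjusted over the list alone (median 1.39, adjusted p = 9.63e-07, and adjusted p = 0.415 with an estimated correlation). Tbx3 rose by 3.94 ± 0.13, Tfcp2l1 by 2.87 ± 0.17, Esrrb by 2.33 ± 0.22, Klf4 by 1.88 ± 0.14 and Nanog from 157 ± 24.1 to 356 ± 22.8 CPM, and Dppa3 fell by 5.77 ± 0.58. Of the Wnt targets 3 of 14 rose and 3 fell (adjusted p = 0.519). Axin2 went from 36.3 ± 10.4 to 115 ± 11.2 CPM, the homeobox gene Cdx1 rose by 5.07 ± 0.30 and the transcription factor gene Sp5 fell by 1.58 ± 0.28. Formative and primed genes were lower, 11 of 13 (adjusted p = 3.52e-05, and adjusted p = 0.415 with an estimated correlation), with Pou3f1 at -5.53 ± 0.21, Fgf5 at -3.54 ± 0.34, Otx2 at -2.84 ± 0.32 and Dnmt3b at -2.13 ± 0.13. Tet2 rose by 2.80 ± 0.24. MEK-ERK targets went both ways, with Spry4 (2.34 ± 0.17) and Etv4 (2.37 ± 0.14) higher and Dusp4 lower (-2.79 ± 0.27), 5 of 14 each way, with 6 lower adjusted over the list alone (adjusted p = 0.841).

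Primitive endoderm genes were higher in the knockout, 9 of 14 with 3 lower (median 2.42, adjusted p = 0.0106, and adjusted p = 0.505 with an estimated correlation). Hnf4a, Sox17 and Gata6, transcription factors of that lineage, rose by 7.44 ± 0.55, 4.09 ± 0.43 and 3.91 ± 0.30. Of the mesendoderm genes 8 of 11 fell and 2 rose (adjusted p = 0.00449, and adjusted p = 0.415 with an estimated correlation), with Wnt3 at -7.29 ± 0.50 and Mixl1 at -4.40 ± 0.29. Of the trophoblast genes 5 of 8 fell and 1 rose (adjusted p = 0.0249, and adjusted p = 0.423 with an estimated correlation), with Krt8 at -5.87 ± 0.40 and Krt18 at -6.50 ± 0.39. Of the neuroectoderm genes 5 of 8 fell and 1 rose (adjusted p = 0.017, and adjusted p = 0.415 with an estimated correlation). All 4 two-cell-like genes fell (adjusted p = 0.0106, and adjusted p = 0.423 with an estimated correlation), with Zscan4f at -4.98 ± 0.72. Of the fibroblast genes 10 of 12 fell, 11 adjusted over the list alone (median -1.34, adjusted p = 0.000585, and adjusted p = 0.415 with an estimated correlation), with Tagln at -3.68 ± 0.28, Acta2 at -2.20 ± 0.26 and Thy1 not passing at -0.23 ± 0.26. Of the p53 targets 8 of 12 fell and 1 rose (adjusted p = 0.0206, and adjusted p = 0.634 with an estimated correlation), a call lost without unmodified replicate 1 (adjusted p = 0.0922) or knockout replicate 2 (0.0968).

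Hprt (chromosome X, 52988137 to 53021659) was among the 5 genes allowed by the naming rule that rose most in the knockout (6.11 ± 0.19). Others were Bhmt (8.16 ± 0.59) and the imprinted zinc finger gene Plagl1 (6.83 ± 0.34). The guanylate-binding protein gene Gbp2 was among those that fell most (-9.31 ± 0.54). Ctnnb1 (0.07 ± 0.09), Myc (0.14 ± 0.14), Brd2 (0.02 ± 0.10) and Brd3 (-0.03 ± 0.12) did not pass. Sox2 (0.79 ± 0.23) and Pou5f1 (0.48 ± 0.17) passed, but Sox2 lost its call without unmodified replicate 1 (adjusted p = 0.147) or knockout replicate 2 (0.0686) and Pou5f1 with RLE scaling (0.0664), a stricter filter (0.0504) or any 1 library left out (0.0675 to 0.188). In all, 6790 genes passed, 3219 higher and 3571 lower, and 1117 and 2374 at a log2 fold change of at least 1. The count was 4512 without unmodified replicate 1 and 4526 without knockout replicate 1. The differences of the knockout and of 2iL from the same control libraries correlated across genes with Pearson r = 0.612 and Spearman rho = 0.575. Unchanged groups simulated from the mean levels of those controls gave r = 0.441 ± 0.014 (SD of 20 simulations). The covariance was 1.687 against 0.074 simulated, a difference of 1.613. The simulations thus lack the levels of 2iL and knockout cells, so their values are a rough guide only. Both comparisons called 2478 genes lower (948 for independent lists) and 2017 higher (910), and 437 went opposite ways (1864). The simulations gave 0 shared calls, but they held no changed genes, so they do not show how many shared calls the common controls add. The 2 control libraries were not divided between the 2 comparisons, so part of the excess may come from the shared controls.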

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

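The 4 tests of explanations for the naive genes were chosen only after the result was seen, whereas the tests of the differences between responses were set before it. The response to JQ1 differed between 2iL and serum/LIF in 706 genes and between knockout and unmodified cells in 742. With no low-count filter these counts were 1478 and 2011. For the first difference, the count was 468 without serum/LIF DMSO replicate 2, 383 without 2iL JQ1 replicate 1 and 330 without 2iL JQ1 replicate 2. For the second, it was 340, 489, 403 and 1779 without unmodified DMSO 1, DMSO 2, JQ1 1 or JQ1 2, and 226, 397, 212 and 232 without knockout DMSO 1, DMSO 2, JQ1 1 or JQ1 2.

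Between the media, 7 lists differed: naive pluripotency (adjusted p = 2.87e-12, 13 of 16 genes passing, 15 adjusted over the list alone), glycolysis (1.21e-07, 7 of 14, 10 over the list alone), mesendoderm (0.000122, 2 of 11, 4 with 1 lower over the list alone), fibroblast (0.0073) and BET, elongation and Mediator (0.0281) tested higher in 2iL as lists, and cholesterol synthesis (0.00526, 1 of 15, 5 over the list alone) and germline (0.0125, 2 of 12) lower. By edgeR 0 of 12 fibroblast genes were higher, with or without adjustment, and 1 lower, and by DESeq2 0 either way. Of 17 BET list genes 0 passed by edgeR, 2 were higher unadjusted, and 1 was higher by DESeq2. No list kept its call with an estimated correlation. Under 1 CPM with DMSO, with little room to fall, were 11 of 12 fibroblast and 6 of 11 mesendoderm genes in 2iL and 4 of 12 germline genes in serum/LIF. The calls of 3 lists were lost without 1 library: cholesterol synthesis without serum/LIF JQ1 replicate 1 (0.118), germline without serum/LIF DMSO replicate 1 (0.0789), serum/LIF JQ1 replicate 2 (0.0508) or 2iL DMSO replicate 1 (0.091), and the BET list without serum/LIF DMSO replicate 1 (0.0944), serum/LIF JQ1 replicate 2 (0.218), 2iL DMSO replicate 1 (0.091) or 2iL JQ1 replicate 1 (0.0866). The BET list also lost its call with fry (0.129) and with no low-count filter (0.0701). Single genes with a higher log2 response in 2iL were Prdm14 (4.11), Nr5a2 (3.15), Nr0b1 (2.27), Nanog (1.82), Klf4 (1.26), Ceacam1 (4.76), Dnmt3l (3.54), Pfkl (1.58), Ldha (1.184), Eomes (2.27) and Nodal (1.46), and those with a lower one were Plekha6 (-5.62) and Mmp14 (-4.60). Esrrb (1.27) lost its call without 5 of the 8 libraries: serum/LIF DMSO replicate 2 (0.0876), serum/LIF JQ1 replicate 1 (0.0597), 2iL DMSO replicate 1 (0.0779), 2iL JQ1 replicate 1 (0.0801) or 2iL JQ1 replicate 2 (0.102).

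Between knockout and unmodified cells, naive pluripotency (adjusted p = 0.000576, 5 of 16 genes higher and 1 lower, 9 and 2 adjusted over the list alone), two-cell-like (0.00126), p53 target (0.0067), glycolysis (0.0067) and mesendoderm (0.0125, 1 of 11 higher, 3 with 1 lower over the list alone) tested higher in the response of the knockout as lists, and cholesterol synthesis (1.13e-06, 7 of 15, 12 over the list alone) and DNA methylation (0.0272, 1 of 8) lower. By edgeR 0 of 4 two-cell-like, 0 of 12 p53 and 0 of 14 glycolysis genes passed over all genes. Adjusted over the list alone, 0, 2 and 2 of them were higher. Unadjusted, 0, 6 and 5 of them were higher, and by DESeq2 0, 3 and 4. The two-cell-like genes had little room to fall with JQ1 in the knockout, since all 4 were already lower there with DMSO (median -4.88) and under 1 CPM, as were 4 of 11 mesendoderm genes. No list kept its call with an estimated correlation. Calls were lost without 1 library for p53 targets (unmodified DMSO replicate 1, 0.0573, unmodified JQ1 replicate 2, 0.0638, or knockout DMSO replicate 2, 0.0513), mesendoderm (unmodified JQ1 replicate 2, 0.0937) and DNA methylation (unmodified DMSO replicate 1, 0.102, unmodified JQ1 replicate 2, 0.0862, knockout DMSO replicate 1, 0.0659, or knockout JQ1 replicate 1, 0.064). The p53 call was also lost with fry (0.144). Single genes were Nr5a2 (1.94), Tdh (1.81), Nanog (1.58), Sox21 (3.85), Fgf8 (3.60), Notum (2.82), Kbtbd11 (-4.32), Atp2a3 (-4.14), Dhcr7 (-1.02), Srebf2 (-0.96) and Foxd3 (-3.12). Klf4 (0.99) lost its call without unmodified DMSO replicate 2 (0.0532), knockout DMSO replicate 1 (0.082), knockout JQ1 replicate 1 (0.0693) or knockout JQ1 replicate 2 (0.0658), and Brd2 (-0.54) without any library but unmodified JQ1 replicate 2 (0.064 to 0.173).

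Naive genes fell with JQ1 in serum/LIF and differed from 2iL. A smaller share of ES cells with JQ1 would lower general pluripotency genes too, and their median was 0.03 (SE 0.141) against -1.003 for naive genes. The deepest control library is not the whole source, since without it 12 naive genes were still lower and 14 had a higher response in 2iL (adjusted p = 7.27e-15). Whether loss of GSK3 activity is enough for part of the smaller fall cannot be told apart from another difference between the cell lines, as the labels do not state the parental line of either. The median naive difference was 0.999 (SE 0.303) in the knockout and 1.475 (SE 0.152) in 2iL, but both are taken from the same 4 unmodified serum/LIF libraries, so chance there moves both alike. Whether it is enough for all of the smaller fall stays open too. The response in 2iL minus that in the knockout, which share no library, had a median of 0.664 (SE 0.291) over naive genes. It was 0.563 to 0.703 with 1 of those 8 libraries left out, so it did not stay beyond 2 standard errors. Each SE here comes from bootstrap draws of the list's genes, which are not independent replicates, and leaves out the spread between libraries.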

How the results depend on the processing

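The fit without mitochondrially encoded genes and that of genes at 5 CPM or more in unmodified 2iL cells with DMSO were chosen only after the result was seen. No gene or list named turned its direction in a call, but the majority between media did: 4802 higher and 4509 lower became 4262 and 4874 with RLE and 4068 and 4555 with DESeq2, as the median of all genes went from 0.038 to -0.03 and -0.031. The counts below are for JQ1 in serum/LIF unless another comparison is named. With only the libraries compared, the count was 2245, and 431 for the difference in 2iL. The same restriction raised it from 5799 to 7329 in the knockout and from 742 to 758 for the difference there. With a log2 fold change of at least 1, counts were 1684, 2389 in 2iL, 2475 in the knockout, 5374 between media and 3491 between genotypes. With genes at 5 CPM or more in 2iL, they were 2164, and 4198 between genotypes (fewer genes tested). With no filter, the difference was 1478 in 2iL and 2011 in the knockout, where DESeq2 gave 1350, and the correlations across genes of serum/LIF with 2iL and with the knockout were 0.272 and 0.218. The stricter filter gave 0.625 for the latter. The cause was not tested for these. With an estimated correlation 0 lists were called. Fry lost 5 of 55 list calls and made 12 others. Of 179 named gene calls, 0 were lost with DESeq2, 3 with RLE, 1 with no filter and 7 with only the libraries compared, and 1 of 178 with the stricter filter. Of the named genes that did not pass, 4 passed with DESeq2, 1 with RLE, 12 with no filter, 1 with the stricter filter and 7 with only the libraries compared.

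Leaving out 1 library gave 1927 to 2822 calls for JQ1 in serum/LIF, 2530 to 4632 in 2iL, 3186 to 3998 in the knockout, 7694 to 8395 between media, 4512 to 5651 between genotypes, 330 to 784 for the difference in 2iL and 212 to 1779 for that in the knockout. The correlation of serum/LIF with 2iL was 0.482 to 0.532, that with the knockout 0.393 to 0.486, and that of medium with genotype 0.553 to 0.622. It gave 47 to 56 lists, -1.68 to -1.43 for Gsk3a and -0.79 to -0.52 for Gsk3b.

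With the replicate number as a block the counts in the same order were 4011, 5147, 6222, 9572, 7071, 920 and 1110, with 55 lists, and 4953 higher and 4619 lower between media. With it 0 of the 179 named gene calls were lost and 8 others passed: Tagln in serum/LIF, Esrrb and Gsk3a in 2iL, Gsk3a and Gsk3b in the knockout, Klf5 between media, and Esrrb and Myc in the difference in the knockout. The labels do not say that the numbers pair the samples, and with 2 per group the values do not settle it. Residuals of like-numbered replicates correlated from -0.186 to 0.185 over 15 pairs of groups, over 0.1 in 6 and under -0.1 in 2. Between JQ1 and DMSO they correlated by 0.185 in serum/LIF, 0.118 in 2iL and 0.117 in the knockout.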

Other observations

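The tests on fibroblast transcripts and Hprt, and the histone, imprinted and chromosome X genes, were chosen only after the result was seen. JQ1 raised 385 genes in all 3 settings, against 24 for independent lists, and lowered 822, against 73. Among those higher in all were Txnip, an inhibitor of glucose uptake (1.65 ± 0.12 in serum/LIF, 1.35 ± 0.12 in 2iL and 1.26 ± 0.12 in the knockout, log2 ± SE), Sesn3, a stress-response gene (1.32 ± 0.19, 1.43 ± 0.19 and 1.42 ± 0.19), and the replication-independent histone gene H3f3b (1.20 ± 0.14, 0.94 ± 0.14 and 1.30 ± 0.14). Of 16 histone genes at 5 CPM or more in a group, 7 rose in serum/LIF, 7 in 2iL and 14 in the knockout, 6 in all 3, and 1 fell in 2iL. Among those lower in all were Krt42 (-5.62 ± 0.55, -3.61 ± 0.48 and -4.94 ± 0.52) and the costimulatory ligand gene Cd80 (-4.48 ± 0.46, -3.85 ± 0.33 and -5.29 ± 0.43). With JQ1 in serum/LIF, Krt42 stood at 0.186 and Cd80 at 0.114 CPM, near the floor of 3 counts. The size of their falls is therefore uncertain.

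Of 26 imprinted genes 22 fell and 2 rose in 2iL against serum/LIF, with a median log2 of -2.43 (unadjusted camera p = 1.6e-07, and p = 0.016 with an estimated correlation). Being unadjusted and from a list chosen after the data were seen, such p-values cannot be set against those of the 19 lists. Peg10 stood at 1200 ± 473 and 4.69 ± 0.768 CPM, and Igf2, a growth factor gene, at 170 ± 28.7 and 0.161 ± 0.0321 CPM, while Plagl1 rose from 3.74 ± 0.425 to 60.5 ± 20.1 CPM (SD, n = 2). In the knockout 16 fell and 4 rose, with a median of -0.80 (unadjusted camera p = 0.00343, and p = 0.113 with an estimated correlation). Fibroblast genes fell in both comparisons as well, 12 of 12 and 10 of 12 (11 adjusted over the list alone), so a part of the imprinted change that is carried by such cells is not excluded. The 379 chromosome X genes at 5 CPM or more in unmodified serum/LIF cells with DMSO had a median log2 of -0.24 in 2iL, where the medians of the 19 autosomes ran from -0.05 to 0.16. In the knockout it was -0.21, against -0.09 to 0.09, and both comparisons share those controls.

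Fibroblast transcripts fell with JQ1 in serum/LIF. A loss of feeder cells alone would move them all alike if all of them came from feeder cells. Their log2 changes differed beyond their errors, with a heterogeneity of 11.27 per degree of freedom over 11 degrees around a weighted mean of -1.01. This does not exclude such a loss, since some of the transcripts may come from other cells. Whether the transcripts come from feeder cells or from differentiated ES cells cannot be told apart, since 11 of 12 were under 1 CPM in 2iL, which differs from serum/LIF in both.

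Hprt was high in the knockout libraries, with 118 CPM or more in each of the 4 and at most 2 CPM in each of the 8 unmodified ones. Feeder fibroblasts in the knockout libraries would raise fibroblast genes, whose median was -1.34 (SE 0.435). A different parental line, such as one lacking Hprt among the unmodified cells, and a rise of Hprt with loss of GSK3 activity cannot be told apart, since the knockout and any difference of line fall in the same 4 libraries and the labels name no line. Hprt changed by -2.17 (SE 0.309) in 2iL, which holds a GSK3 inhibitor, but from at most 2 CPM, and cells that lack the gene would not raise it either way.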
